A study of Mus musculus with 6 samples.

How the data were processed

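Messenger RNA was sequenced from 6 cultures of mouse (C57BL/6) megakaryocytes. Per the labels' protocols, femoral bone marrow was cultured for 7 days with stem cell factor, erythropoietin at 1 unit per ml and thrombopoietin (TPO) at 20 ng per ml, raised to 50 ng per ml on day 2 and 100 ng per ml on day 4. No sorting of the cells is described. Libraries were made with a poly-A selecting kit (TruSeq RNA v2) that does not mark the strand. The submitters' processing notes name TopHat2 2.0.8, HTSeq 0.5.4, DESeq2 without a version, and mouse build mm10, without the role of each.

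The deposited file of each sample holds raw counts per Ensembl gene for 38483 genes, followed by 5 tallies of reads that were not assigned. A further deposited table holds the authors' own comparison of dKO with WT as a log2 fold ratio per gene, and the authors give with it a p-value and a false discovery rate; the test and filter behind it are not stated. Its gene symbols and annotation were used here, and its ratios, p-values and false discovery rates only for a side by side comparison. Reads that met no gene made up 5.59% to 10.7% of the reads assigned, ambiguous or without a gene, highest in the September libraries. Ambiguous reads made up 2.41% to 2.74%, mitochondrial genes 2.32% to 3.37% of gene counts, and the 20 most abundant genes 8.23% to 11.3%.

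Genes with a count numbered 24395. Those kept by edgeR's filterByExpr (minimum count 10, minimum total 15), 12658 genes, were tested. Of their identifiers, 12559 matched GENCODE M21, which gave exons and coordinates on GRCm38, the same build as mm10. Gene symbols, also those used to match the gene lists, came from the authors' deposited table. Counts were scaled by the trimmed mean of M values (TMM) and are printed as CPM, counts of a gene over a library's scaled total. The planned test was edgeR 4.0.16's quasi-likelihood test (robust glmQLFit) in R 4.3.3 with genotype as the only term, WTlox 3, 6 and 10 against dKO 4, 5 and 9, and Benjamini-Hochberg adjustment over all tested genes at 0.05. It is two-sided. Standard errors of log2 fold changes are the size of the change over the square root of the F statistic. The 2 groups share no replicate numbers, so no pairs were formed, and the labels do not say whether each library comes from a separate mouse. If some share a mouse, the p-values measure only the spread between cultures. No libraries were copies of one another: among pairs, the squared difference over its counting variance was at least 20.9 per gene, where counting error alone gives about 1.

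Isolation date goes with age in the labels, with 2 libraries of each genotype in July and 1 of each in September. A fit with isolation date as a term was planned as an alternative, and its genes are named by the same rule, which was applied to it after the data had been seen. The biological coefficient of variation was 0.311 with genotype as the only term and 0.202 with isolation date as a term.

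The design, the gene lists and the rule for named genes were fixed before the data were examined. The rule names Sp1 and Sp3; the 8 largest rises and 8 largest falls past the threshold with a mean of at least 5 CPM and no overlap between the groups; in each function list the 3, and in each cell type list the 2, members with the smallest adjusted p past the threshold, or else the most abundant member; and Mylk, Pf4, Itga2b, Gp1ba, Nfe2, Gata1 and Myh9. The 16 function lists and 10 marker lists cover platelet receptors, granules, cytoskeleton, signalling, transcription factors, general cell functions and other bone marrow cells. Cxcl15, Hbb-bt, Hbb-bs and Ahsp are in a list without a match in the counts by symbol. Lists with at least 5 tested genes, 24 in number, were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 24. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes move one way and its mixed form whether they change in either direction. Neither compares a list with other genes. Where genes are said to rise or fall adjusted over a list alone, the Benjamini-Hochberg adjustment was made within that list, without correction over the lists. That adjustment is apart from the planned one over all tested genes, and it does not make a gene one of those called.

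The alternatives were DESeq2 1.42.0's Wald test, its type of size factors in edgeR, no filter on low counts, a minimum mean of 5 CPM, limma-voom, the 20 most abundant genes left out, isolation date as a term, the July libraries alone, and each library left out in turn. Repeats of these with isolation date as a term were chosen after seeing the data.

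The tests were tested on simulated data of 12658 genes with the same design, in which 200 genes were changed by 2-fold or 4-fold. A further 40 genes were shifted as a set by a log2 fold change of -0.5. With genotype as the only term, 5% of 2-fold and 63% of 4-fold changes were recovered, with 0 false calls. With isolation date as a term, 59% and 88% were recovered, and 13 of 162 calls were false, a larger share than the 0.05 aimed at. The simulated counts were drawn from the fit with isolation date as a term, with its date differences kept. The higher recovery with that term was therefore built in and does not show which fit suits the real data better. Totals of 8383225 to 16302988 counts limit genes of low abundance most. The kit does not mark the strand, so counts of genes whose exons overlap those of another gene are less certain.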

Results

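Poly-A selected RNA was sequenced from megakaryocytes, the platelet-producing cells of bone marrow, grown from mice of 2 genotypes. Both genotypes carry floxed alleles of Sp1 and Sp3, which encode zinc-finger transcription factors binding GC-rich promoters. In the group labelled dKO, Cre recombinase under the promoter of the platelet gene Pf4 is present as well, so that both genes are to be deleted in megakaryocytes; the group labelled WTlox lacks Cre. Each group holds 3 libraries, WTlox 3, 6 and 10 and dKO 4, 5 and 9. Gene counts totalled 15079558, 12124752 and 8383225 in the WTlox libraries and 12312631, 16302988 and 8555159 in the dKO-labelled libraries, in that order. RNA of WTlox 3 and 6 and dKO 4 and 5 was isolated on 30 July 2012 at week 12 of age, and that of WTlox 10 and dKO 9 on 3 September 2012 at week 17. The first principal component, with 52.2% of the variance, separated the 2 dates. Its scores were 46.0 and 58.3 in dKO 9 and WTlox 10 and ran from -46.8 in WTlox 6 to 4.21 in dKO 5 in July. The next component held 21.1% and separated the genotype labels. Its scores were 18.9, 23.4 and 25.1 in WTlox 3, 6 and 10 and -24.3, -42.4 and -0.65 in dKO 4, 5 and 9. Xist, the RNA that silences an X chromosome in females, was measured at 1666 and 1377 CPM (a gene's counts scaled to a common library total) in the September libraries WTlox 10 and dKO 9 and at 0.577 to 1.19 CPM in the 4 July libraries. Isolation date, age and the level of Xist therefore went together, and genotype was balanced over them.

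**Figure D1:**
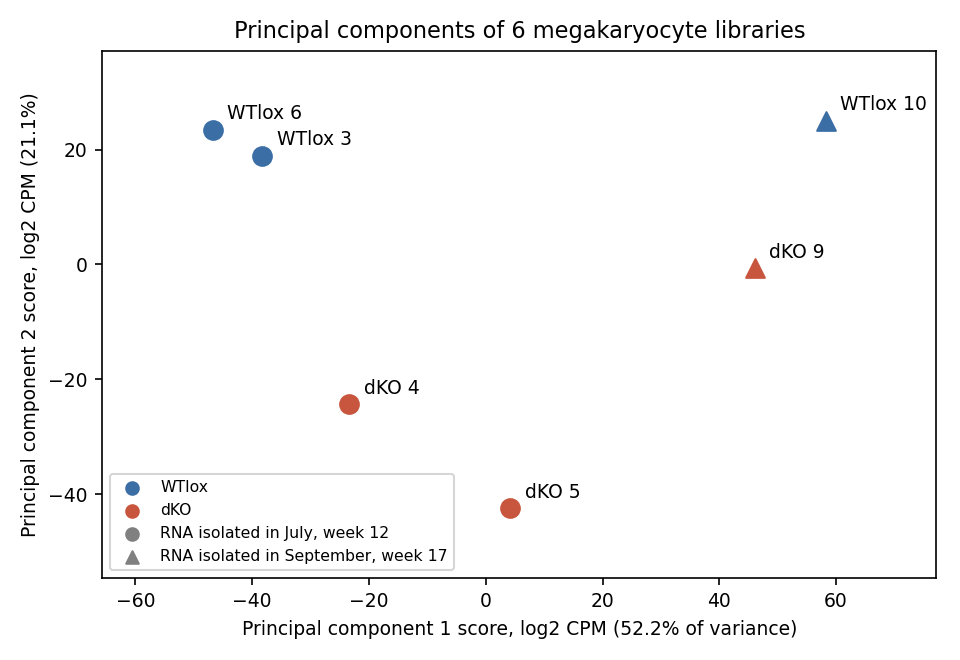
The 6 libraries on the first principal components of log2 CPM, with the share of variance on each axis (52.2% and 21.1%); colour marks the genotype label and shape the isolation date. The September libraries WTlox 10 and dKO 9 lie apart from the 4 July libraries along the first axis. Along the second axis the WTlox libraries lie above the dKO-labelled libraries.

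The comparison of dKO-labelled with WTlox libraries asks which megakaryocyte transcripts depend on Sp1 and Sp3. The counts of the targeted genes differed in opposite directions, Sp1 higher and Sp3 lower in the dKO-labelled libraries, and Sp3 did not pass the test in either fit. Sp1 (ENSMUSG00000001280, GRCm38 chromosome 15, 102406143 to 102436404) was measured at 108, 71.2 and 120 CPM in WTlox 3, 6 and 10 and at 214, 278 and 296 CPM in dKO 4, 5 and 9. Its mean was 100.0 ± 25.6 CPM (SD, n = 3) in WTlox and 262 ± 43.1 CPM in dKO-labelled libraries, a ratio of 2.63. With genotype as the only term the log2 fold change of Sp1 was 1.39 ± 0.23 (SE) with an adjusted p = 0.133. With isolation date as a term it was 1.40 ± 0.19 with an adjusted p = 0.0289, and all 3 dKO-labelled libraries lay above all 3 WTlox libraries. Sp3 (ENSMUSG00000027109, chromosome 2, 72936427 to 72980446) was measured at 97.6, 83.7 and 98.8 CPM in WTlox 3, 6 and 10 and at 71.9, 61.7 and 54.5 CPM in dKO 4, 5 and 9. Its log2 fold change was -0.57 ± 0.15 with an adjusted p = 0.295, and -0.58 ± 0.14 with an adjusted p = 0.115 with isolation date as a term. The counts cover whole genes and include exons outside the floxed part, and the floxed exons are not given in the sources used here, so neither gene shows how far the deletion went. The authors' deposited table gives log2 ratios of 1.30 for Sp1, with a false discovery rate of 2.88e-07, and -0.55 for Sp3, with one of 0.00637, both under 0.05.

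With genotype as the only term, 4 of 12658 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and in each of them the 3 libraries of one group lay outside the range of the other. Cxcl3 (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600), a chemokine that attracts neutrophils and lies 12720 bp from Pf4, rose from 3.98 ± 1.47 CPM (SD, n = 3) to 114 ± 37.3 CPM, a 28.5-fold change with a log2 fold change of 4.83 ± 0.37 (SE) and an adjusted p = 0.0394. Ephb1 (ENSMUSG00000032537, chromosome 9, 101922128 to 102354693), a receptor tyrosine kinase for ephrins, rose from 0.262 ± 0.0679 to 7.06 ± 2.06 CPM, with a log2 fold change of 4.72 ± 0.43 and an adjusted p = 0.0457. Its mean is under the 5 CPM asked of named genes, so Ephb1 was chosen after its values were seen. Layn (ENSMUSG00000060594, chromosome 9, 51054640 to 51077094), which encodes the hyaluronan-binding membrane protein layilin, fell from 19.0 ± 4.04 to 1.54 ± 0.414 CPM, with a log2 fold change of -3.61 ± 0.31 and an adjusted p = 0.0394. Pfkm (ENSMUSG00000033065, chromosome 15, 98092589 to 98132451), the muscle-type subunit of the glycolytic enzyme phosphofructokinase, fell from 81.4 ± 5.51 to 27.2 ± 2.70 CPM, with a log2 fold change of -1.58 ± 0.13 and an adjusted p = 0.0394. Exons of Pfkm overlap those of Senp1, and exons of Ephb1 overlap those of Gm26846. Across all tested genes the groups did not overlap for 1739, or 13.7%. Chance gives 10% if all libraries are exchangeable, and less for genes that differ strongly between the dates, over which genotype was balanced. The 4 calls were kept when WTlox 10 was left out, which gave 12 genes, and none was kept when any other library was left out; limma-voom called 0 genes, with 1170 at an unadjusted p under 0.05, and DESeq2 called 311.

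Genes with a role in platelets were among those that fell once isolation date was a term. That fit called 203 genes, 70 higher and 133 lower in the dKO-labelled libraries, the 4 genes above among them. Of these, 151 differed by more than 2-fold, 52 higher and 99 lower. Tbxa2r, the receptor for thromboxane A2, fell from 56.0 ± 18.3 CPM (SD, n = 3) to 8.69 ± 2.68 CPM, with a log2 fold change of -2.68 ± 0.17 (SE) and an adjusted p = 0.0082. Alox12, the platelet 12-lipoxygenase, fell from 1006 ± 436 to 181 ± 131 CPM, with a log2 fold change of -2.72 ± 0.33 and an adjusted p = 0.0237. Other large falls were those of Ptprn (log2 fold change -4.27), Layn (-3.58), Mest (-3.38), Tspan17 (-3.00), Acer2 (-2.97) and Exoc3l4 (-2.54), with adjusted p from 0.0085 for Exoc3l4 to 0.0395 for Mest. Acer2 encodes an alkaline ceramidase and Tspan17 a tetraspanin. Among genes with a mean of at least 5 CPM and no overlap between the groups, the largest rise after that of Cxcl3 was that of Amhr2 (ENSMUSG00000023047, chromosome 15, 102445367 to 102454633), the receptor for anti-Müllerian hormone, which lies 8963 bp from Sp1. Amhr2 rose from 1.79 ± 0.771 to 15.7 ± 2.73 CPM, with a log2 fold change of 3.21 ± 0.31 and an adjusted p = 0.0136. Gm9796 (2.57), Gm14304 (2.50), Atp8b5 (2.40), Dennd6b (2.32), Gm16758 (2.09) and Serpina3b (1.85) followed. Serpina3b belongs to a cluster of similar serpin genes between which reads are hard to assign, and exons of Mest, Ptprn, Exoc3l4 and Dennd6b overlap those of another annotated gene. The fit called 0 genes without WTlox 3 and 0 without WTlox 6, with 1488 and 1244 at an unadjusted p under 0.05, and 26 without dKO 4, and DESeq2 with the same term called 676. The July libraries alone gave 219 genes, 98 higher and 121 lower. The September pair, with 1 library of each genotype, allows no test on its own.

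**Figure D2:**
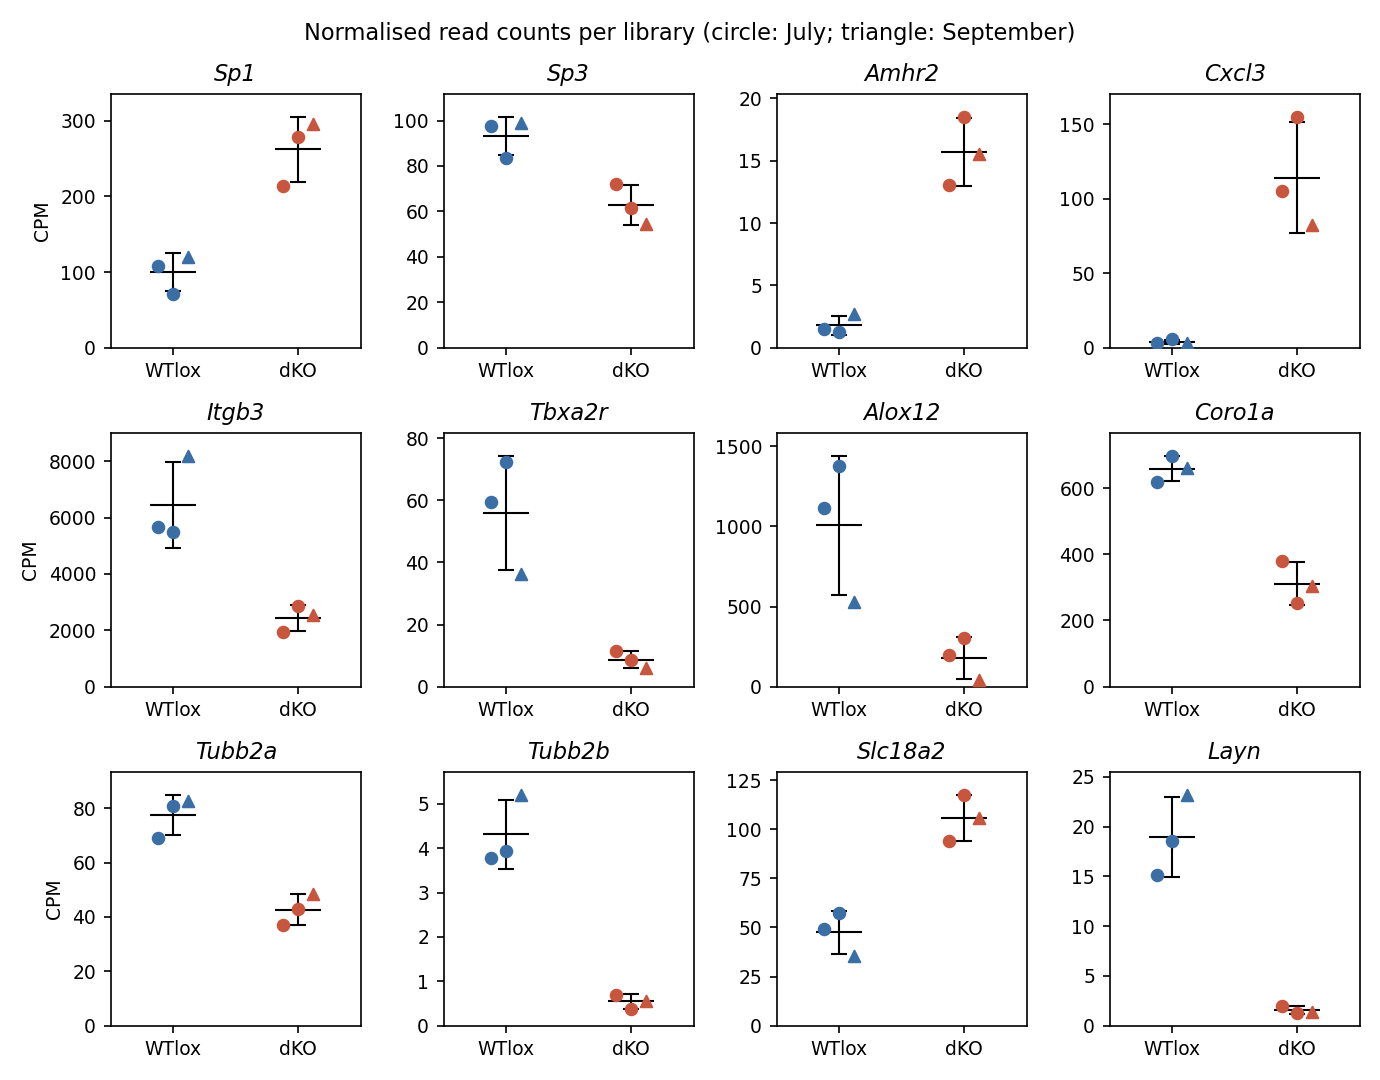
CPM (vertical axes, from 0) of 12 named genes, with 1 point per library; colour marks the genotype label, shape the isolation date, horizontal lines the group means and error bars the SD (n = 3). For Sp1 the 3 dKO-labelled libraries lie between 214 and 296 CPM and the 3 WTlox libraries between 71.2 and 120 CPM.

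Among platelet surface receptors, the thromboxane receptor Tbxa2r and the integrin chain Itgb3 fell, and most members did not pass. Of 37 genes, 0 rose, 2 fell and 35 did not pass with isolation date as a term; adjusted over the list alone, 3 fell, Tbxa2r, Itgb3 and Esam. Itgb3, the beta chain of the fibrinogen receptor, fell from 6446 ± 1524 CPM (SD, n = 3) to 2449 ± 463 CPM, with a log2 fold change of -1.37 ± 0.23 (SE), an adjusted p = 0.0459 and no overlap between the groups. Its partner Itga2b had a log2 fold change of -0.04 ± 0.23 with genotype as the only term, and Gp1ba, the ligand-binding chain of the von Willebrand factor receptor, one of 0.35 ± 0.23, neither passing. The median log2 fold change of the list was -0.07 in each fit, with 13 genes above 0 with genotype as the only term and 12 with isolation date as a term. By camera at the preset correlation the list was lower with an adjusted p = 0.0385 with genotype as the only term and 0.0326 with isolation date as a term. These became an adjusted p = 0.997 with an estimated correlation and an adjusted p = 0.972 with an estimated correlation and isolation date as a term.

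In the platelet granule list, with isolation date as a term, 1 of 45 genes rose, 1 fell and 43 did not pass; adjusted over the list alone, 3 rose and 2 fell. Slc18a2, the vesicular transporter that loads serotonin into dense granules, rose from 47.5 ± 11 CPM (SD, n = 3) to 106 ± 11.7 CPM, with a log2 fold change of 1.18 ± 0.17 (SE) and an adjusted p = 0.0331. Hps6, needed to form dense granules, fell from 15.8 ± 1.76 to 7.64 ± 1.93 CPM, with a log2 fold change of -1.07 ± 0.17 and an adjusted p = 0.0421; for both genes the groups did not overlap. Thbs1, the granule protein thrombospondin 1, was measured at 9314 ± 683 CPM in WTlox and 4805 ± 2372 CPM in dKO-labelled libraries. It did not pass, with an adjusted p = 0.539 with genotype as the only term and 0.240 with isolation date as a term. Pf4 had a log2 fold change of -0.18 ± 0.26 and did not pass. The list as a whole did not pass, with an adjusted p = 0.554 with genotype as the only term and 0.702 with isolation date as a term.

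In the list of the actin and myosin cytoskeleton, which drives platelet release and contraction, Myl9, Limk1 and Coro1a fell. Of 53 genes, 0 rose, 3 fell and 50 did not pass with isolation date as a term; adjusted over the list alone, 5 fell, Myl9, Limk1, Coro1a, Arpc1b and Rock2. Myl9, a regulatory light chain of non-muscle myosin, fell from 9.52 ± 4.98 CPM (SD, n = 3) to 0.460 ± 0.107 CPM, with a log2 fold change of -4.34 ± 0.39 (SE) and an adjusted p = 0.0125. Coro1a, an actin-binding coronin whose exons overlap those of Bola2, fell from 659 ± 39.1 to 312 ± 63.8 CPM, and Limk1, a kinase of the actin-severing protein cofilin, fell from 45.0 ± 5.24 to 23.5 ± 4.44 CPM. Their log2 fold changes were -1.08 ± 0.18 with an adjusted p = 0.0485 for Coro1a and -0.95 ± 0.16 with an adjusted p = 0.0459 for Limk1; in all 3 genes the groups did not overlap. Mylk, the myosin light chain kinase, was measured at 426 ± 62.3 and 307 ± 41.4 CPM. Its log2 fold change was -0.47 ± 0.17 with an adjusted p = 0.518 with genotype as the only term. With isolation date as a term it did not pass either, with an adjusted p = 0.198. Myh9, the heavy chain of non-muscle myosin, had a log2 fold change of -0.35 ± 0.27 and Tln1, encoding talin, one of -0.06 ± 0.29; neither passed. By camera at the preset correlation the list was lower with an adjusted p = 0.00082 with genotype as the only term and 0.00133 with isolation date as a term. These became an adjusted p = 0.970 with an estimated correlation and an adjusted p = 0.972 with an estimated correlation and isolation date as a term.

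In the list of microtubules and the proplatelet scaffold, Tubb2a and Tubb2b fell: with isolation date as a term 0 of 35 rose, 2 fell and 33 did not pass, and adjusted over the list alone 4 fell, Tubb2b, Tubb2a, Map1a and Tuba4a. Tubb2a fell from 77.6 ± 7.41 CPM (SD, n = 3) to 42.7 ± 5.80 CPM, with a log2 fold change of -0.87 ± 0.12 (SE) and an adjusted p = 0.0312. Tubb2b fell from 4.31 ± 0.782 to 0.546 ± 0.162 CPM, with a log2 fold change of -2.95 ± 0.36 and an adjusted p = 0.0237; in both genes the groups did not overlap. These tubulin genes are near-identical neighbours, so reads are hard to assign between them. Tuba4a, an alpha tubulin abundant in platelets, was measured at 1772 ± 380 and 986 ± 325 CPM, without overlap between the groups. It did not pass, with an adjusted p = 0.490 with genotype as the only term and 0.0755 with isolation date as a term. By camera at the preset correlation the list was lower with an adjusted p = 0.0136 with genotype as the only term and 0.0086 with isolation date as a term. These became an adjusted p = 0.891 with an estimated correlation and an adjusted p = 0.972 with an estimated correlation and isolation date as a term.

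Platelet activation signalling was lower as a list by camera with isolation date as a term (adjusted p = 0.0333) and did not pass with genotype as the only term (adjusted p = 0.0952). The first became an adjusted p = 0.972 with an estimated correlation. Of its 52 genes 0 rose, 1 fell, which was Alox12, and 51 did not pass; adjusted over the list alone, 2 fell, Alox12 and Pla2g4a, which releases arachidonic acid from membranes. Rap1b, a small GTPase of integrin activation, had a log2 fold change of -0.22 ± 0.26 with genotype as the only term and did not pass.

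Of 25 targets of p53 and apoptosis genes, 21 had a log2 fold change below 0 with genotype as the only term, with a median of -0.41. In the fit with isolation date as a term 0 rose and 0 fell over all genes, while adjusted over the list alone 5 fell, Bcl2l11, Sesn2, Fas, Casp3 and Phlda3. Bcl2l11 encodes the pro-apoptotic protein Bim and had a log2 fold change of -1.49 with an adjusted p = 0.0608 over all genes. Ccng1, the most abundant member, was measured at 799 ± 302 and 607 ± 26.3 CPM (SD, n = 3). By camera at the preset correlation the list was lower, with the smallest adjusted p of the 24 lists tested, adjusted p = 0.000203 with genotype as the only term and 0.000841 with isolation date as a term. These became an adjusted p = 0.891 with an estimated correlation and an adjusted p = 0.972 with an estimated correlation and isolation date as a term. Fry and camera with an estimated correlation ranked the lists differently.

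Of the chemokine genes at the Pf4 locus, Cxcl3 rose and the other 5 tested did not pass. Cxcl5 and Ppbp, which lie with Pf4 and Cxcl3 in one cluster, had log2 fold changes of -0.07 ± 0.17 (SE) and -0.24 ± 0.32 with isolation date as a term, and Cxcl1 and Cxcl2 ones of -1.02 ± 0.59 and -0.14 ± 0.66. The list was higher by camera with an adjusted p = 0.0154 with genotype as the only term and 0.0086 with isolation date as a term, while its median log2 fold change was -0.12 and its mean 0.50 in the first fit, so the call rests on Cxcl3. These became an adjusted p = 0.926 with an estimated correlation and an adjusted p = 0.972 with an estimated correlation and isolation date as a term.

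**Figure D3:**
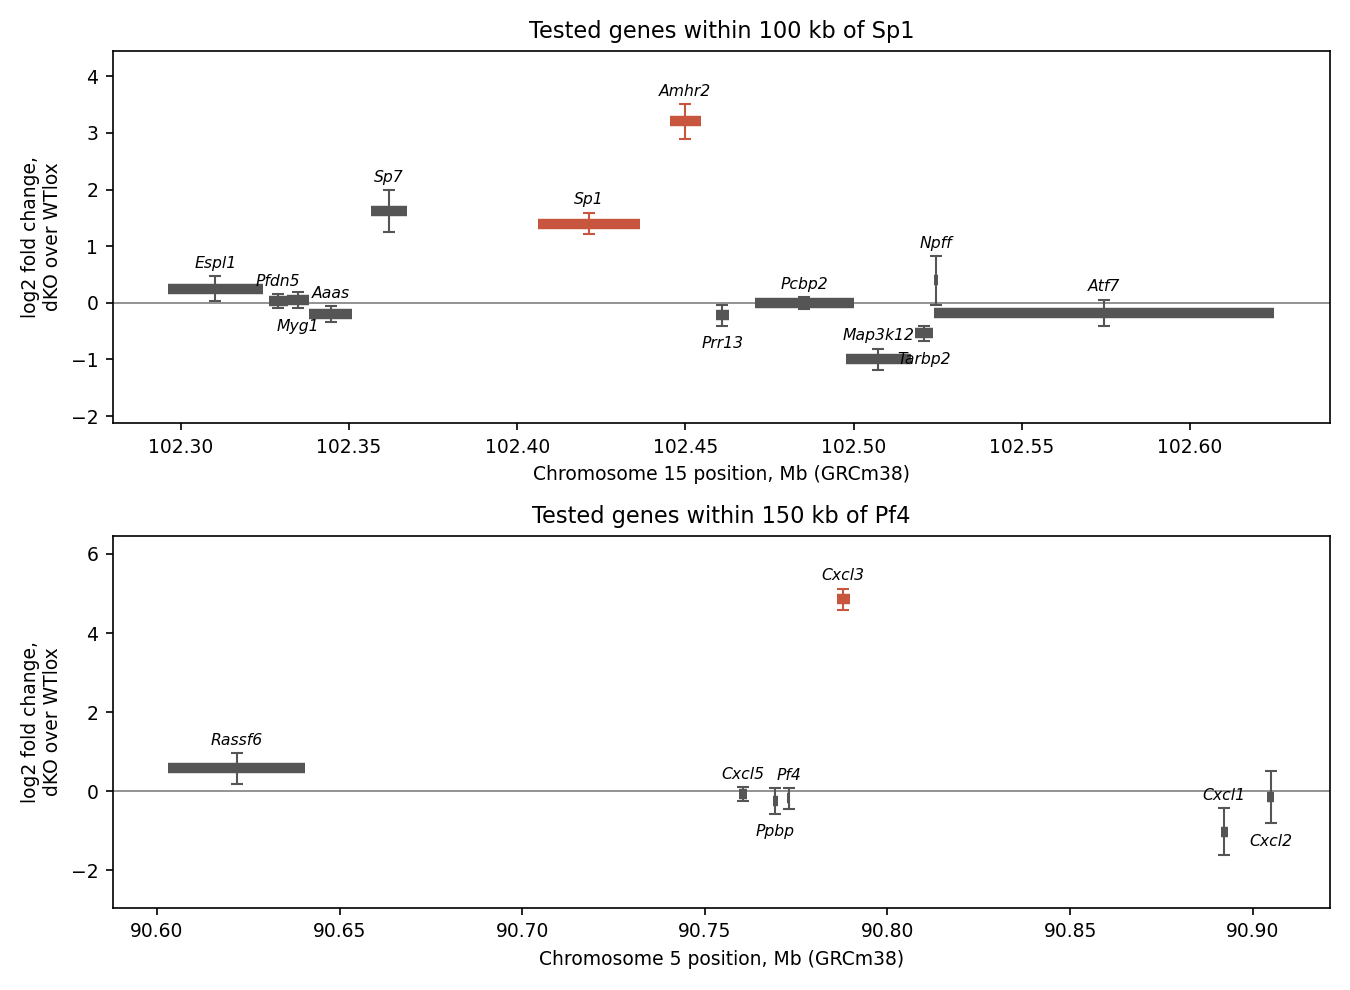
Log2 fold changes of dKO-labelled over WTlox libraries (vertical axis, isolation date as a term) of tested genes within 100 kb of Sp1 on chromosome 15 and within 150 kb of Pf4 on chromosome 5 (GRCm38 position in Mb). Each bar spans a gene, error bars are standard errors, and red marks genes past an adjusted p of 0.05: Sp1 at 1.40 and Amhr2 at 3.21 in the upper map, and Cxcl3 at 4.86 in the lower map.

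No transcription factor of the megakaryocyte lineage passed the test: 0 of 26 passed in either fit and the list had an adjusted p = 0.367 by camera with genotype as the only term. Nfe2 had a log2 fold change of 0.05 ± 0.21 (SE) and Gata1 one of -0.43 ± 0.24, neither passing. In the Sp/Klf family, with isolation date as a term, Sp1 rose, 0 fell and 15 did not pass; adjusted over the list alone 2 rose, Sp1 and Sp4, and 4 fell, Sp3, Klf10, Klf16 and Klf6. That list had an adjusted p = 0.750 by camera with genotype as the only term.

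None of the remaining function lists passed by camera with genotype as the only term, and 0 of their genes passed in either fit. Adjusted p was 0.988 for the cell cycle, 0.606 for sterol and fatty acid synthesis, 0.965 for the interferon response, 0.965 for the unfolded protein response, 0.367 for oxidative phosphorylation, 0.147 for cytosolic ribosomal proteins and 0.988 for N-glycosylation and GPI anchors. Their most abundant genes had log2 fold changes of -0.09 ± 0.48 (SE) for Ccnd2, 0.11 ± 0.40 for Hmgcr, 0.04 ± 0.19 for Stat1, 0.03 ± 0.17 for Calr, -0.16 ± 0.14 for Atp5b, -0.14 ± 0.16 for Rpl4 and -0.07 ± 0.14 for Rpn1. For the cell cycle and N-glycosylation lists the camera direction was up while the medians were -0.07 and -0.01. By the test for change in either direction (fry, mixed), 7 of the 24 lists passed in each fit, and by the test for change in one direction 0 passed.

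Markers of other bone marrow cells did not pass as lists with genotype as the only term, and 0 of their genes passed in either fit. Adjusted p by camera was 0.147 for progenitor, 0.853 for erythroid, 0.853 for mast cell and basophil, 0.965 for neutrophil, 0.988 for monocyte and macrophage, 0.554 for eosinophil, 0.965 for dendritic cell and 0.148 for stromal and endothelial markers. For the mast cell and basophil list and the monocyte and macrophage list, camera's direction was up while the medians were -0.22 and -0.27. Progenitor markers were below 0 for 13 of 14 genes, with a median log2 fold change of -0.53, eosinophil markers for 5 of 5, with a median of -0.80, and stromal and endothelial markers for 9 of 11, with a median of -1.0. These medians lie further from 0 than those of the receptor list (-0.07), the actin and myosin list (-0.14), the microtubule list (-0.12) and the p53 and apoptosis list (-0.41). Stromal collagen RNA differed between libraries: Col1a1 was measured at 341, 801 and 7.88 CPM in WTlox 3, 6 and 10 and at 161, 56.6 and 11.3 CPM in dKO 4, 5 and 9. Its log2 fold change was -2.33 ± 1.45 (SE) with an adjusted p = 0.816, and in July it was lower in both dKO-labelled libraries than in both WTlox libraries, as were Tbxa2r, Itgb3, Myl9, Limk1, Coro1a, Tubb2a and Tubb2b. Those genes were named because they were lower in the dKO-labelled libraries, so the shared order is no evidence of a link to Col1a1. The most abundant genes of the other marker lists had log2 fold changes of -0.05 ± 0.31 for Angpt1, 0.09 ± 0.18 for Tfrc, -0.23 ± 0.47 for Slc6a4, -0.55 ± 0.83 for Mpo, 0.22 ± 0.20 for Lyz2, -0.34 ± 0.64 for Prg2 and 0.37 ± 0.33 for Bst2. B cell markers had 2 tested genes and T and NK cell markers 1, too few for a list test; Cd79b was measured at 2.10 ± 1.5 and 1.90 ± 0.853 CPM (SD, n = 3) and Nkg7 at 31.6 ± 24.5 and 13.1 ± 11.6 CPM.

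The authors' deposited table lists 1237 genes at a false discovery rate under 0.05, 572 higher and 665 lower in dKO. Of the authors' calls 1216 were tested here, and in the authors' deposited table and in the fit with isolation date as a term all 1216 had the same sign. All 203 genes called with that term are among the calls of the authors' deposited table. Across genes, which are not independent replicates, Pearson's correlation of log2 fold changes with the authors' deposited table was 0.959 with genotype as the only term and 0.972 with isolation date as a term. The authors' deposited table belongs to the same series, so the shared signs and calls are no independent evidence for these genes.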

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

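The test of a date by genotype difference was chosen after the difference between dates had been seen. Gm3608, a predicted gene, was singled out because its genotype change differed between the dates: the log2 fold change of dKO-labelled over WTlox libraries was 6.45 higher in September than in July, with an adjusted p = 0.0126 by edgeR's quasi-likelihood test of the interaction. It was measured at 25.6 and 23.2 CPM in WTlox 3 and 6, at 12.2 and 13 CPM in dKO 4 and 5, at 0.667 CPM in WTlox 10 and at 30.6 CPM in dKO 9. The difference rests on WTlox 10, with 5 counts, and on dKO 9, with 270, since September has 1 library of each genotype; the spread behind the test comes from the July libraries alone, and the September libraries are assumed to vary like them. Gm3608 was 1 of 12658 genes to pass, with 1271 at an unadjusted p under 0.05, and the smallest adjusted p of this test among the genes named by the rule was 0.368.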

How the results depend on the processing

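With genotype as the only term, DESeq2 called 311 genes (105 higher, 206 lower), no filter gave 81 (26 higher, 55 lower), a minimum mean of 5 CPM gave 3 (1 higher, 2 lower), limma-voom gave 0 (0 higher, 0 lower), isolation date as a term gave 203 (70 higher, 133 lower) and the July libraries alone gave 219 (98 higher, 121 lower). Size factors of the DESeq2 type and leaving out the 20 most abundant genes each gave 4. Leaving out 1 library gave 0 to 12 genes (0 to 6 higher, 0 to 6 lower), with 12 without WTlox 10 and 0 without each of the others. Lists past the threshold, 5 as reported, numbered 8 with no filter, 3 with a minimum mean of 5 CPM, 3 with limma-voom, 3 without the 20 most abundant genes, 9 in July alone, 0 with an estimated correlation, 0 with fry and 4 to 8 without 1 library. Sp1 passed with DESeq2 (log2 fold change 1.40, adjusted p = 5.84e-05), with no filter (1.40, adjusted p = 0.0129), with isolation date as a term (1.40, adjusted p = 0.0289) and in July alone (1.46, adjusted p = 0.0412), and ranged from 1.20 to 1.56 without 1 library. Sp3 kept its direction and did not pass under these alternatives.

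With isolation date as a term, DESeq2 called 676 genes (274 higher, 402 lower) and no filter gave 1195 (439 higher, 756 lower), each including all 203 reported. The other scalings, filters and limma-voom gave 196 to 218 genes. Leaving out 1 library gave 0 to 253 genes (0 to 113 higher, 0 to 140 lower), with 0 without WTlox 3, 0 without WTlox 6, 26 without dKO 4, 143 without dKO 5, 237 without dKO 9 and 253 without WTlox 10. Lists past the threshold, 6 as reported, numbered 0 with an estimated correlation, 0 with fry and 5 to 10 without 1 library. Sp1 ranged from 1.23 to 1.57 without 1 library and did not pass without WTlox 3, WTlox 6 or dKO 4. Sp3 passed with DESeq2 (-0.57, adjusted p = 0.0297) and with no filter (-0.57, adjusted p = 0.00809), and ranged from -0.68 to -0.44 without 1 library. Of 26 genes followed in this fit, 0 reversed under any alternative. These were named genes already past the threshold in it, with Sp1 and Sp3, so few reversals could arise. The 25 of them that had passed, all but Sp3, no longer passed without WTlox 3, nor did they without WTlox 6.

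Genes whose direction turned did not pass in any setting. In July alone the log2 fold changes were 0.046 for Pf4, 0.21 for Itga2b, 0.21 for Tln1, 0.16 for Rap1b, 0.16 for Ccnd2, -0.054 for Calr, 0.41 for Angpt1 and 0.20 for Slc6a4. With isolation date as a term they were 0.0030 for Ccnd2 and 0.028 for Angpt1. Without 1 library they ranged from -0.19 to 0.12 for Itga2b, -0.13 to 0.19 for Nfe2, -0.23 to 0.27 for Tln1, -0.35 to 0.087 for Rap1b, -0.47 to 0.56 for Ccnd2, -0.24 to 0.60 for Hmgcr, -0.12 to 0.18 for Stat1, -0.077 to 0.13 for Calr, -0.22 to 0.35 for Angpt1, -0.059 to 0.19 for Tfrc, -0.53 to 0.43 for Slc6a4, -0.81 to 0.075 for Prg2, -0.63 to 0.28 for Cd79b and -0.057 to 0.61 for Bst2. July alone and the runs without 1 library use fewer samples; for the other changes the cause was not tested. No paired analysis was possible because the groups share no replicate numbers. Depth of 8383225 to 16302988 counts limits genes of low abundance.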

Other observations

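The comparison of dates below, and the tests of exchanged labels, of the ratio of Amhr2 to Sp1, of Cxcl3 and its neighbours and of stromal RNA, were chosen after the results had been seen. Isolation date went with differences in genes of sterol and fatty acid synthesis, the interferon response and the cell cycle: 1076 genes differed between the 2 September and the 4 July libraries in the fit with both terms, 647 higher and 429 lower in September, by edgeR's quasi-likelihood test. Of 28 genes of sterol and fatty acid synthesis 14 were higher and 0 lower, among them Lss, lanosterol synthase, at 51.5 CPM in July and 185 CPM in September (log2 fold change 1.83 ± 0.14, SE), Elovl6 (1.55) and Hmgcr, the rate-limiting enzyme of cholesterol synthesis (0.99). The list had an adjusted p = 1.53e-13 by camera, which became an adjusted p = 0.691 with an estimated correlation. Of 25 interferon response genes 10 were higher and 0 lower, such as Ddx58, a sensor of viral RNA (1.61), Usp18 (1.33) and Irf9 (1.17), with an adjusted p = 3.59e-09 for the list, which became an adjusted p = 0.691 with an estimated correlation.

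Cell cycle genes were lower in September, 17 of 42 with 2 higher, such as Cdc25b (log2 fold change -1.25), Mad2l1 (-1.12) and Pcna (-0.85), with an adjusted p = 2.41e-10, which became an adjusted p = 0.998 with an estimated correlation. Of 20 erythroid markers 9 were lower and 0 higher, such as Hba-a1 (-1.58) and Hbb-b1 (-1.30), with an adjusted p = 1.66e-08, which became an adjusted p = 0.691 with an estimated correlation. Stromal and endothelial markers were lower with an adjusted p = 0.0369, which became an adjusted p = 0.998 with an estimated correlation. Xist was higher in September (10.62) and the Y-linked gene Ddx3y lower (-9.70), so date, age, sex of the animals as read from these genes, and depth cannot be told apart in these 6 libraries. Genes on X and Y alone are argued against as the whole difference, since they made up 5.58% of the 1076 genes.

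Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave 4 or more genes with genotype as the only term, the real one, and the highest other gave 2. With isolation date as a term, 1 of the 6 splits that keep the dates balanced gave as many as the real 203, and the highest other gave 0. Both sets of splits are too few for a share under 0.05.

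Differences confined to the July cultures are argued against by the September pair, in which 87.2% of the genes called in July alone had the same sign, 191 of 219, against 51.6% of all tested genes. The 98 genes higher in July had a median log2 ratio of 0.85 in September, closer to 0 than their July median of 1.61. For the 121 lower genes the median was -1.20 in September and -1.53 in July. These sizes are on unlike measures. The September ratios are differences of log2 CPM with a prior count of 2, which draws ratios of low counts towards 0, and the July values are edgeR's fitted log2 fold changes. The genes were also chosen by their July changes, so the smaller September sizes do not show a weaker difference in September.

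Sp1 counts were higher in all 3 dKO-labelled libraries although the label names a deletion of Sp1, and Amhr2, which lies 8963 bp away on the same strand, was higher too. Labels exchanged between a library of each group were looked for in Sp3, the other targeted gene, for which 0 libraries lay inside the other group's range. This cannot decide the question, since Sp3 passed in neither fit and the groups did not overlap for 13.7% of all tested genes. A fixed share of Sp1 transcripts running on into Amhr2 is argued against by the ratio of Amhr2 to Sp1 counts, which was 3.45 times as high in the dKO-labelled libraries, with 5.25 to 6.67 Amhr2 counts per 100 Sp1 counts against 1.36 to 2.22. A regional change cannot be told apart from a change of these genes alone, since the other 11 tested genes within 100 kb went both ways. With isolation date as a term their median log2 fold change was -0.0066 with an SD of 0.651, and 0 of them passed. They ranged from -0.996 for Map3k12 to 1.62 for Sp7, which lies 38961 bp from Sp1. Sp7 rose by more than the 1.40 of Sp1, from 245 to 760 counts, with an adjusted p = 0.103 by edgeR's quasi-likelihood test. Continued or altered transcription of the undeleted part of Sp1 stays open and was not tested, since the files used here hold counts of whole genes. An exchange of the whole groups stays open too, since the targeted genes go opposite ways. Sp3 was lower in the dKO-labelled libraries, at 54.5 to 71.9 CPM against 83.7 to 98.8 CPM in the WTlox libraries, without passing, while Sp1 was higher.

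Cxcl3 rose next to Pf4, whose promoter drives Cre. Extra copies of the whole Pf4 locus that transcribe Cxcl5 like the native copies are argued against by Cxcl5. Its log2 fold change had an upper 95% limit of 0.34, below the 0.58 that 3 such copies in place of 2 would give. Counts of RNA do not show silent copies. Extra copies of a stretch with Cxcl3 but without Cxcl5 stay open too, since these genes lie on opposite sides of Pf4. A joint rise of the inducible chemokines nearby is argued against by Cxcl1 and Cxcl2, whose higher upper limit was 1.45, below the lower limit of 4.22 for Cxcl3. An effect of the Cre transgene on Cxcl3 itself and an effect of the deletion of Sp1 and Sp3 both stay open, since every dKO-labelled library carries Cre and no WTlox library does.

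In July Col1a1 was lower in the dKO-labelled libraries, and so, by the way they were chosen, were the 121 genes called lower there. RNA of stromal cells in the WTlox libraries is argued against as the whole cause by the September pair, in which Col1a1 was at 7.88 CPM in WTlox 10 and 11.3 CPM in dKO 9. In that pair the 121 genes called lower in July had a median log2 ratio of -1.20 with an SE of 0.137, and 108 of them were below 0. The SE is taken over genes, which are not independent replicates, and does not measure the spread between cultures. Another difference in cell composition or maturation between the cultures, and a direct effect of the genotype, stay open and were not tested.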
